A study of Mus musculus with 11 samples.

How the data were processed

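RNA of the hippocampus of 11 female F1 mice was measured by polyadenylated, directional RNA sequencing, with 1 library per mouse and no pooling. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20, trimmed with Trim Galore 0.6.6, aligned to GRCm38 with HISAT2 2.1.0, handled with SAMtools 1.10 and counted per gene with featureCounts of Subread 2.0.0. The annotation release, the strand setting of the counting, whether mates or fragments were counted and the method of assigning reads to alleles were not given in the sources used here. The authors deposited 3 tables: counts per gene, TPM per gene, and counts per gene and allele with 2 columns per mouse. The deposited counts are whole numbers without normalization. The deposited TPM values, made by the authors, divide the counts by 1 length per gene and scale each library to the same sum, and the 10 genes highest in TPM, mostly short RNAs, take 31.35% to 56.14% of it. The allele columns of the allelic table are named i4fb and cast per the file headers, and i4fb was taken as the BL6 copy.

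The tables hold 55401 genes, of which 55141 were matched by identifier to GENCODE M21 for positions and gene types, and 107 symbols are used by more than 1 identifier. Depth ran from 111.1 to 214.8 M counts per library, and allelic depth from 39.7 to 76.9 M. The smallest chi-square per gene between libraries of an age group was 56.2, where 1 is sampling noise. The counts of no pair of libraries of the same age group were thus alike within sampling noise. Old and young libraries were not compared in this way. Protein-coding genes took 88.59% to 92.69% of counts and mitochondrial genes 0.00%, so the list of mitochondrially encoded genes could not be tested.

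Groups were taken from the sample labels: old or young, and BL6 or CAST mother. Total counts were fitted in R 4.3.3 with edgeR 4.0.16 quasi-likelihood tests after TMM scaling and the filterByExpr filter, with terms for cross and age. The interaction was a separate fit with its own filter. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 are called. SE is the absolute log2 fold change over the square root of F. Means and SD are of TMM-scaled CPM.

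Allelic counts of autosomal genes with a mean of at least 10 allelic reads per mouse were fitted in edgeR with terms for mouse, maternal allele, BL6 allele and each allele term by age, with the library size of both columns set to the mouse total. X-linked genes were fitted apart with the X-linked total of each column as library size. The silent-allele share is the mean per mouse over imprinted core genes with at least 20 allelic reads in every mouse and a mean silent share under 10%, which kept 21 genes and left out 12. The X share is the median per mouse of the BL6 percent over 520 genes with at least 20 allelic reads in every mouse, without Xist and the escape list. Shares were compared by two-sided exact permutation over all 462 splits, for which the smallest possible p is 0.0022.

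Of 46 gene lists fixed before the files were opened, 45 could be tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Camera adjusted p is over all lists tested, and "adjusted over the list alone" is the edgeR p adjusted over the members of a list. The oxidative phosphorylation list has 30 measured entries because a symbol has 2 identifiers. Predicted genes were compared with mitochondrial transcripts by blastn 2.17.0, and a match needed 80% identity over 100 bases. Tables and figures were made with data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

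The genes named were set by a rule written before the files were opened. For age these are the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 CPM, without predicted or unnamed genes, and for cross and interaction 5 each way, or the 3 with the smallest p where none passes. Of each list described, up to 4 members with the smallest adjusted p are named, and all methylation enzymes. For alleles these are up to 8 imprinted genes per parent by adjusted p, up to 5 outside the lists by size of effect, up to 10 by smallest p in each term by age, and the 5 largest strain effects each way. For the X these are Xist, the measured escape genes, and called genes or the 3 with the smallest p. Marker genes per library, the neighbours of a called gene and single genes marked as such were chosen after their values were seen. Some genes that the rule names are not reported here.

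The tests were tested on simulated data with the sample sizes of the real ones. In total counts simulated with the spread of the real fit, 14.3%, 56.2% and 94.4% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 6 false calls among 30289 genes. In simulated allelic counts, whose spread was an assumed setting, 99.1% and 100% of changes of 1 and 3 on the log2 scale were recovered, with 16 false calls among 24707 genes. On X-linked counts simulated with the same setting all changed genes were recovered with 1 false call among 701 genes. In total counts only genes with a mean of at least 1 CPM were changed. In autosomal and X-linked allelic counts only genes with at least 100 allelic reads on average and no strong strain bias were changed. Recovery among the other genes was thus not measured. A simulated list raised 1.5-fold had an adjusted p of 9.7e-27 in camera, and 0 of 45 random lists passed. In random groupings of the real mice, by contrast, 6 to 27 of the fixed lists passed. The simulation therefore does not show how often lists pass by chance in the real counts.

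Alternatives tried were DESeq2 1.42.0, size factors of the RLE kind, no filter and a filter at 1 CPM in 5 libraries, a threshold of 0.01, models without the second term, single crosses and ages, limma on deposited TPM, other minima of allelic reads (50 on average, 10 in every mouse), limma on logit shares, other library sizes, other gene sets and summaries for the shares, permutation within groups, and leaving out each mouse. Leaving out the 3 libraries with the highest striatal markers, the striatal marker mean or the Malat1 share as a term, permuting the X share within age groups, and leaving Dlk1 out of the silent-allele share were added after seeing the data. DNA methylation, repeats and other brain areas of the series were not analysed here.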

Results

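Polyadenylated RNA was sequenced from the hippocampus of 11 female F1 mice bred in reciprocal crosses of C57BL/6 (BL6) and CAST/EiJ (CAST), a wild-derived inbred strain whose many sequence differences from BL6 let reads be assigned to a parental chromosome. Of these mice, 5 were old (101 to 104 weeks) and 6 were young (8 to 9 weeks). A BL6 mother had borne 3 of the old and 3 of the young mice, and a CAST mother the other 2 old and 3 young mice. Each mouse carries 1 BL6 and 1 CAST copy of each autosome, and comparing the crosses separates the effect of the parent of origin from that of the strain. The study asked how aging affects genomic imprinting, X-chromosome inactivation and the enzymes of DNA methylation in the brain. Total counts ran from 111.1 to 214.8 M per mouse over 55401 genes, and 37881 to 39702 genes were detected in each mouse. Counts assigned to an allele ran from 39.7 to 76.9 M, 35.12% to 36.44% of the total, and 50.39% to 51.1% of them were BL6.

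The libraries were alike in broad terms, with correlations of log2 values between 0.9774 and 0.9947, but the dissections held differing amounts of neighbouring tissue. The striatal dopamine receptor gene Drd2 stood at 74.4 CPM in young replicate 2, at 60.9 CPM in young replicate 6 and at 32.0 CPM in old replicate 3, against 1.82 CPM in old replicate 1. The choroid plexus gene Ttr ran from 4.17 CPM in young replicate 5 to 880 CPM in old replicate 2. The thalamic markers Prkcd and Tcf7l2 were highest in young replicate 1, at 213 and 88.6 CPM. Prox1, a marker of dentate granule cells, ran from 56.6 CPM in young replicate 6 to 216 CPM in young replicate 5, and Fibcd1, a marker of CA1 pyramidal cells, from 41.1 to 192 CPM. Malat1, a nuclear long non-coding RNA, took 1.19% ± 0.4 of counts in old mice (SD, n = 5) and 1.57% ± 0.48 in young mice (SD, n = 6). The axis with most variance, 34.767% of the total, did not fully separate the ages. It set old replicate 3 and young replicates 1, 2, 3 and 6 apart from the other libraries. These had 41.1 to 95.7 CPM of Fibcd1, against 115 to 192 CPM in the others. Their Prox1 was 56.6 to 108 CPM, against 114 to 216 CPM in the others.

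The comparison of old with young mice asked which genes change with age in total expression. Genes of activated microglia and of complement were higher in old mice. C4b, complement component 4b (chromosome 17, 34728380 to 34743882), rose 5.82-fold, from 23.3 ± 4.65 CPM in young mice (SD, n = 6) to 136 ± 19.96 CPM in old mice (SD, n = 5), a log2 change of 2.54 with an SE of 0.15 (edgeR adjusted p = 3.2e-05). Itgax, the integrin CD11c of activated microglia and dendritic cells, rose 8.22-fold, from 0.134 ± 0.0395 to 1.104 ± 0.327 CPM (edgeR adjusted p = 8.1e-04). Clec7a, a receptor for fungal glucans that marks activated microglia, rose 7.28-fold, from 0.0503 ± 0.0227 to 0.380 ± 0.0551 CPM (edgeR adjusted p = 0.00419). Gpnmb, a glycoprotein of lipid-laden phagocytes, rose 3.10-fold (edgeR adjusted p = 0.0228). Cdkn2a, which encodes cell cycle inhibitors that accumulate in senescent cells, rose 5.11-fold, from 0.0750 ± 0.0359 to 0.389 ± 0.0455 CPM (edgeR adjusted p = 0.00985).

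Of the 21 measured members of the list of aging and disease-associated microglia, 5 rose over all genes tested (Itgax, Clec7a, Lyz2, Gpnmb and, named after its value was seen, Ccl6), and 13 rose when p was adjusted over the list alone; none fell in either count. The list moved up against other genes, with a median log2 change of 0.48 (camera adjusted p = 9.7e-25, and adjusted p = 0.0298 with an estimated correlation). Of 17 complement genes, 3 rose (C4b, C4a and Itgb2) and 9 rose adjusted over the list alone, C1qa among these at a log2 difference of 0.73. Its median was 0.57 (camera adjusted p = 4.2e-20, and adjusted p = 0.0298 with an estimated correlation). Of 17 genes of MHC class I and antigen processing, H2-D1 (log2 change 0.73) and H2-Q7 (1.60) rose and 12 rose adjusted over the list alone. Its median was 0.68 (camera adjusted p = 1.9e-15, but adjusted p = 0.0549 with an estimated correlation). Of 9 MHC class II genes, Ctss rose, 0.87 on the log2 scale, and 6 rose adjusted over the list alone. Its median was 0.95 (camera adjusted p = 4.6e-09, but adjusted p = 0.0549 with an estimated correlation). C4a and C4b, Lyz1 and Lyz2, and H2-Q6 and H2-Q7 are near-identical pairs between which counts can be misplaced, so the single members are uncertain.

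Of 15 reactive astrocyte genes, C4b rose, and 7 rose adjusted over the list alone. Its median was 0.47 (camera adjusted p = 2.8e-14, but adjusted p = 0.0510 with an estimated correlation). Gfap, the intermediate filament of astrocytes, measured 613 ± 138 CPM in old and 277 ± 84.8 CPM in young mice and did not pass (log2 difference 1.13, edgeR adjusted p = 0.0564); C3, which differed by 1.19 on the log2 scale, and Lcn2 had adjusted p of 0.0943 and 0.0976 in edgeR. Of 12 homeostatic microglia genes none passed over all genes, and 7 rose adjusted over the list alone, among them Siglech, Sall1 and Csf1r at 0.53, 0.44 and 0.41. Its median was 0.41 (camera adjusted p = 9.2e-08, but adjusted p = 0.302 with an estimated correlation). Of 25 lysosomal genes, Ctss rose and 8 rose adjusted over the list alone. Its median was 0.24 (camera adjusted p = 2.3e-07, but adjusted p = 0.382 with an estimated correlation). Of 28 interferon response genes none passed over all genes, and 2 rose adjusted over the list alone, Bst2 and Xaf1 at 0.95 and 0.68. Its median was 0.21 (camera adjusted p = 9.3e-06, but adjusted p = 0.302 with an estimated correlation). Of 12 senescence genes, Cdkn2a rose; adjusted over the list alone, Cdkn2a rose and Lmnb1, the nuclear lamina gene, fell, with a log2 change of -0.43 (list median -0.01 against a mean of 0.16 that Cdkn2a pulled up, camera adjusted p = 0.383).

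Genes of neural progenitors and newborn neurons fell as a list. Top2a, topoisomerase II alpha of dividing cells (chromosome 11, 98992943 to 99024189), fell from 3.24 ± 1.41 CPM in young to 0.527 ± 0.278 CPM in old mice, a log2 change of -2.58 with an SE of 0.38 (edgeR adjusted p = 0.0193). Dcx, doublecortin of migrating young neurons, fell from 31.6 ± 7.94 to 17.6 ± 3.09 CPM (edgeR adjusted p = 0.0400), Draxin, an axon guidance gene, by 2.07 and Eomes, a transcription factor of intermediate progenitors, by 2.29 on the log2 scale (edgeR adjusted p = 0.00834 and 0.0265). Of the 16 measured progenitor and newborn neuron genes, 4 fell and 12 fell adjusted over the list alone. Its median was -0.65 (camera adjusted p = 2.3e-17, and adjusted p = 0.00997 with an estimated correlation). The spindle and cell cycle genes Aspm and Rrm2 fell with log2 changes of -1.73 and -1.21, Cenpf fell from 2.97 to 1.03 CPM, and Rassf10 fell by 1.28 on the log2 scale.

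Gpr17, a receptor of committed oligodendrocyte precursors, fell from 46.8 ± 6.601 to 24.9 ± 3.34 CPM (edgeR adjusted p = 0.00126), and Bmp4, a growth factor of the same stage, with a log2 change of -1.33 (edgeR adjusted p = 0.0338). Of 12 genes of oligodendrocyte precursors and committed cells these 2 fell; adjusted over the list alone 6 fell and 1 rose, Sox10, at 0.51. Its median was -0.23 (camera adjusted p = 7.2e-05, but adjusted p = 0.228 with an estimated correlation). The fibrillar collagens Col3a1 and Col1a2 fell with log2 changes of -1.96 and -1.64 (edgeR adjusted p = 0.0481 and 0.0485). They were the 2 genes that fell of 10 leptomeningeal fibroblast genes, of which 3 fell adjusted over the list alone. Its median was -0.71 (camera adjusted p = 3.1e-05, but adjusted p = 0.349 with an estimated correlation). They were also the 2 that fell of 18 genes of collagen and basement membrane, of which adjusted over the list alone 5 fell and 1 rose, Col6a1, at 0.76. Its median was -0.06 (camera adjusted p = 0.0187, but adjusted p = 0.523 with an estimated correlation).

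Uhrf1, which brings the maintenance methyltransferase to newly copied DNA (chromosome 17, 56303321 to 56323486), fell from 1.88 ± 0.532 CPM in young to 0.719 ± 0.173 CPM in old mice, a log2 change of -1.37 with an SE of 0.24 (edgeR adjusted p = 0.0364), a call lost in 9 of 14 settings. Of 14 measured enzymes of DNA methylation and demethylation it was the 1 that fell over all genes, and adjusted over the list alone Uhrf1 and Tet1 fell, Tet1 from 25.3 ± 2.67 to 18.7 ± 1.70 CPM with a log2 change of -0.44. The list moved down, with a median of -0.19 (camera adjusted p = 1.6e-04, and adjusted p = 0.0298 with an estimated correlation). Among the members that did not pass, Dnmt1 differed by -0.17, Dnmt3a by -0.36, Dnmt3b by -0.11, Tet2 by -0.30, Tet3 by -0.14, Uhrf2 by -0.24, Tdg by -0.10, Smug1 by -0.10, Gadd45a by -0.16, Gadd45b by -0.28 and Gadd45g by -0.21. Dnmt3l was the only member with a positive difference, 1.02, at 0.144 CPM in old and 0.0686 CPM in young mice. Among 17 methyl-CpG readers and imprint maintenance genes none passed over all genes; Zfp57, which protects methylation at imprinted regions, differed by -0.91 (edgeR adjusted p = 0.0521) and fell adjusted over the list alone (list median -0.07, camera adjusted p = 0.0547). None of 15 retroelement silencing genes passed in either count. Its median was -0.09 (camera adjusted p = 0.374).

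In total expression, none of 41 paternally expressed imprinted genes passed over all genes, and 1, Mkrn3, fell adjusted over the list alone, with a log2 change of -0.99. Its median was -0.13 (camera adjusted p = 0.0340, but adjusted p = 0.418 with an estimated correlation). The core of 27 well-known members also had 0 passing genes and Mkrn3 falling adjusted over the list alone. Its median was -0.13 (camera adjusted p = 0.0251, but adjusted p = 0.409 with an estimated correlation). Of 35 maternally expressed imprinted genes none passed over all genes, and 1 rose and 1 fell adjusted over the list alone (median -0.07, camera adjusted p = 0.267); in the core of 13 members, Rian fell adjusted over the list alone, with -0.67. Its median was -0.26 (camera adjusted p = 0.0547). None of 13 genes that escape X inactivation passed. Its median was -0.11 (camera adjusted p = 0.244).

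Several lists of neurons and of neighbouring tissue passed with the preset correlation but not with an estimated one. The libraries lowest in Fibcd1 and Prox1 were old replicate 3 and young replicates 1, 2, 3 and 6. The hippocampal content of the dissections may therefore have differed between the ages. Genes of CA3 and CA2 pyramidal cells had a median of 0.33, with 0 of 12 past the test over all genes and 3 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00813, but adjusted p = 0.418 with an estimated correlation), and those of CA1 a median of 0.44 with 0 of 8 in both counts (camera adjusted p = 0.0256, but adjusted p = 0.523 with an estimated correlation). The 10 striatal genes had a median of -1.46 with 0 past the test in both counts (camera adjusted p = 0.0256, but adjusted p = 0.674 with an estimated correlation), and 2 of the 3 libraries with most Drd2 were young. The median of the 10 genes of neighbouring neocortex was -0.30, with 0 in both counts (camera adjusted p = 0.0322, but adjusted p = 0.459 with an estimated correlation). Of 18 immediate early genes none passed over all genes and Dusp1 fell adjusted over the list alone, with -1.03. Its median was -0.51 (camera adjusted p = 5.4e-05, but adjusted p = 0.443 with an estimated correlation). The 30 cytosolic ribosomal protein genes had a median of 0.18 (camera adjusted p = 2.5e-05, but adjusted p = 0.523 with an estimated correlation), 10 pericyte and smooth muscle genes a median of -0.35 (camera adjusted p = 0.0108, but adjusted p = 0.523 with an estimated correlation), and 5 red blood cell genes a median of 0.55 (camera adjusted p = 0.0322, but adjusted p = 0.523 with an estimated correlation), with 0 genes past the test in both counts for each of these 3 lists.

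Of the other lists tested, none passed as a list. No member passed over all genes or adjusted over the list alone among excitatory neuron (median 0.28), interneuron (-0.01), dentate granule cell (0.20), endothelial (-0.08), choroid plexus (-0.28), ependymal (0.13), lymphocyte (0.00), thalamic (0.02), cholesterol synthesis (-0.01), glutamate receptor (0.11), presynaptic vesicle (0.07) and oxidative phosphorylation genes (0.01). Adjusted over the list alone, 1 gene rose in each of the astrocyte, myelin, circadian clock and heat shock lists, which were Gfap, Hapln2, Bhlhe41 and Bag3, at 1.13, 0.71, 0.39 and 0.67 on the log2 scale. The medians of these lists were 0.07, -0.06, -0.10 and -0.01, and their camera adjusted p ran from 0.0576 to 0.511. The median and the mean differed in sign for heat shock genes (mean 0.10), lymphocyte genes (mean -0.17) and thalamic genes (mean -0.08), and the test followed the mean.

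Across all 30568 genes tested, 104 passed an adjusted p of 0.05, 70 higher and 34 lower in old mice, while DESeq2 gave 272 higher and 250 lower. Of the 104, 102 showed no overlap between the age groups, which 1.85% of all genes did against 0.433% by chance. By the rule for named genes the other large increases were Onecut1, a liver and neural transcription factor gene (chromosome 9, 74861921 to 74891781, log2 change 2.76), Spag6, a gene of motile cilia (1.58), Slc7a15, an amino acid transporter gene (1.58), Zc3hav1, the zinc-finger antiviral protein gene (3.69 CPM in young and 10.3 CPM in old mice), Mettl24 (1.36), C4a (1.28), Lyz2 (1.26) and Pcdhb2, a clustered protocadherin with close paralogs (1.19). Onecut1 overlaps or adjoins 2 predicted genes chosen after their values were seen, Gm20649 and Gm16551, with similar changes of 2.74 and 3.19, and reads of the overlapping parts cannot be told apart because the strand setting of the counting was not given in the sources used here. With all mice kept, 67 of the 104 stayed called with the striatal marker mean as a term and 80 with the Malat1 share as a term. The count of 104 fell to 15 without young replicates 2 and 6 and old replicate 3, and leaving out single libraries gave 14 to 244. Fewer mice also lower the power of the test. All 104 kept their sign without those 3 libraries, but they had been chosen on these same mice. As 102 of them do not overlap between the ages, leaving out libraries could hardly turn their sign, so this is no separate support. Of the 23 lists past the test, 12 moved up and 11 down, and 4 held with an estimated correlation; counting the real one, 13 of 100 random groupings gave 23 or more lists.

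**Figure D1:**
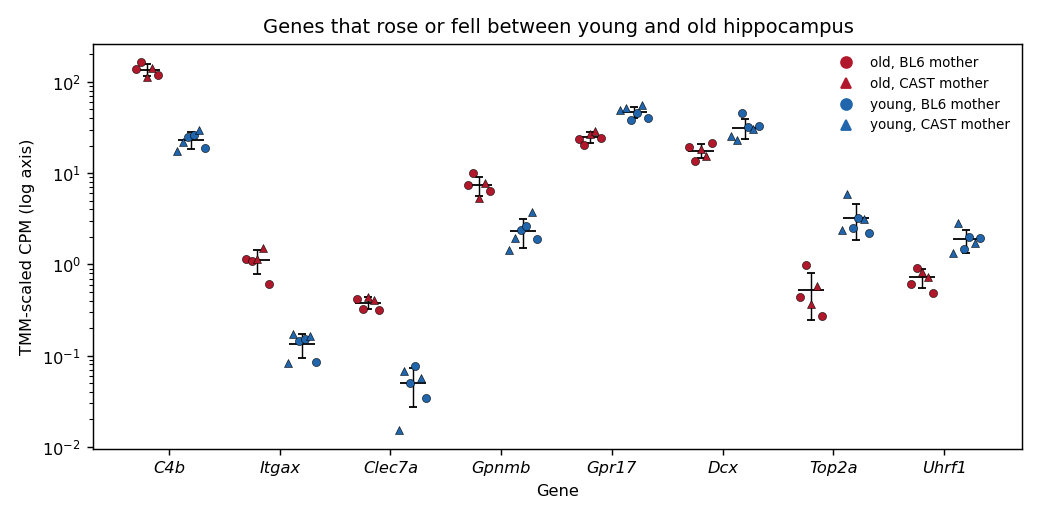
TMM-scaled CPM on a log axis of 8 genes in each mouse, old in red and young in blue, with circles for a BL6 mother and triangles for a CAST mother; bars give the mean and the SD. C4b, Itgax, Clec7a and Gpnmb lie higher in all 5 old mice than in all 6 young mice, and Gpr17, Dcx, Top2a and Uhrf1 lie lower.

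**Figure D2:**
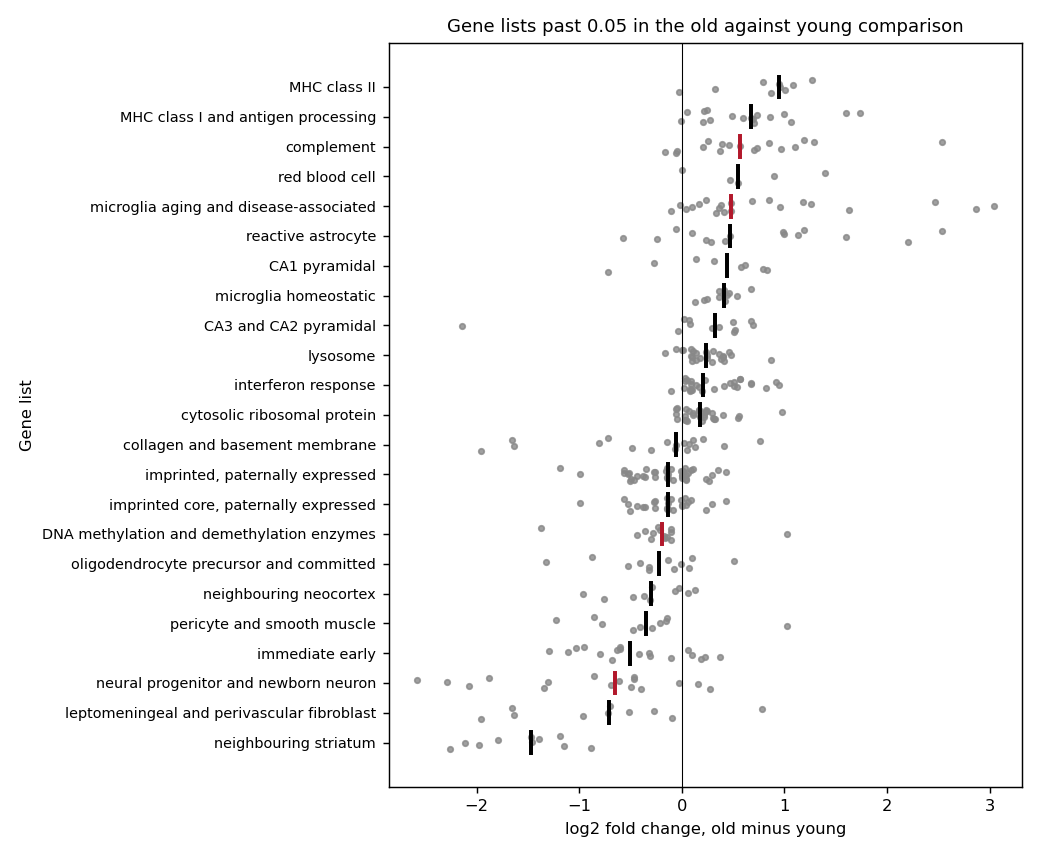
Log2 fold change, old minus young, of each measured member (grey points) of the 23 gene lists past an adjusted p of 0.05 in camera. The upright bar is the median of the list, red for the 4 lists that also passed with an estimated correlation. The median is lowest for striatal genes, -1.46, and highest for MHC class II, 0.95.

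The comparison of mice with a CAST mother and mice with a BL6 mother asked whether the direction of the cross alters total expression. The genes with the strongest evidence were predicted pseudogenes that match mitochondrial transcripts. Gm13341, which matches mt-Co2 at 95.9% identity over 684 bases (chromosome 2, 22587291 to 22587962), measured 141 ± 48.5 CPM with a CAST mother (SD, n = 5) and 0.364 ± 0.120 CPM with a BL6 mother (SD, n = 6), a log2 difference of 8.54 (edgeR adjusted p = 1.4e-07). Gm11410, which matches mt-Cytb, differed by 6.25 and Gm11407, which matches mt-Nd5, by -3.80. A second group lay on chromosome 7 between 59351409 and 60133684, the paternally expressed small nucleolar RNA cluster near Snrpn. Of 48 genes called there, 47 were higher with a CAST mother, and so with a BL6 father.

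Of 30568 genes tested with edgeR, 63 passed an adjusted p of 0.05, 56 higher and 7 lower with a CAST mother. Besides the 48 on chromosome 7, 2 lay in the imprinted cluster of chromosome 12 and 13 elsewhere, of which 9 matched a mitochondrial transcript. Of all 10539 predicted genes tested, 18 matched one (Fisher's exact test, p = 7.9e-24). The 9 are adjoining genes at single places on chromosomes 1, 2 and 4, so they are not independent, as the test takes them to be. The comparison was also chosen after these genes were seen. No gene passed both the symbol and the expression part of the rule for named genes, so the 3 with the smallest p are named. Of the gene lists, 14 passed in camera, 7 higher and 7 lower with a CAST mother, and 0 passed with an estimated correlation, where each had an adjusted p = 0.872 with an estimated correlation. Those with the largest medians were the striatal and thalamic lists, 1.40 and 1.16, with all 10 genes of each higher. Drd2 was highest in young replicates 2 and 6 and old replicate 3, and Prkcd and Tcf7l2 in young replicate 1, and of these libraries all but young replicate 6 had a CAST mother. The endothelial and myelin lists had medians of 0.39 and 0.31, and the lists of pericyte and smooth muscle, oligodendrocyte precursor and collagen genes medians of 0.35, 0.20 and 0.15. The lower lists were immediate early (-0.29), presynaptic vesicle (-0.18), excitatory neuron (-0.17), glutamate receptor (-0.09), oxidative phosphorylation (-0.07), cytosolic ribosomal protein (-0.06) and core paternally expressed imprinted genes (-0.05). None of the members of these 14 lists passed on its own.

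Whether age acted differently in the 2 crosses was tested as an interaction. No gene of 31355 passed in edgeR, with 3711 at an unadjusted p under 0.05, while DESeq2 called 52. The genes with the smallest p, none of which passed, were Ppp1r17, Crtam and Cbln3, with log2 differences of 3.74, 4.29 and 6.34 and edgeR adjusted p of 0.139, 0.324 and 0.418. Cbln3, a gene of cerebellar granule cells, reached 6.07 and 6.82 CPM in young replicates 3 and 4 against 0.173 CPM in old replicate 1. The age differences estimated in each cross alone correlated weakly across 29147 genes (Pearson r = 0.155, Spearman rho = 0.0813), and genes are not independent replicates. All 97 age calls that could be fitted in both crosses had the same sign in each, although they had been chosen on the pooled mice.

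The allelic counts were first compared between the maternal and the paternal copy. Many known imprinted genes were expressed almost wholly from 1 parental copy, and others were biased or did not pass. Among paternally expressed genes, Snrpn, Peg3, Nap1l5 and Kcnq1ot1 had 0.0813% ± 0.0590, 0.0679% ± 0.0526, 0.2198% ± 0.141 and 0.355% ± 0.0883 maternal reads over all mice (SD, n = 11), and Usp29, Peg13 and Snhg14 had 0.213% ± 0.0935, 0.453% ± 0.186 and 2.55% ± 0.439. Commd1, listed as maternally expressed, had 5.28% ± 1.56 maternal reads, but the paternally expressed Zrsr1 lies inside it on the other strand, so the source of its reads is uncertain. Among maternally expressed genes, Rian, Meg3 and Mirg of the chromosome 12 cluster had 99.2% ± 1.26, 99.0% ± 1.63 and 98.9% ± 1.48 maternal reads and Kcnk9, a potassium channel gene, had 96.4% ± 1.81. H13, Ago2 and Trappc9 were biased, with 71.4% ± 1.72, 70.0% ± 3.85 and 62.7% ± 6.24 maternal reads. Rtl1, which the lists hold as paternally expressed, had 98.8% ± 1.28 maternal reads and lies opposite a maternally expressed antisense transcript.

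Of 24707 autosomal genes tested, 216 passed in edgeR, 118 maternal and 98 paternal, and 48 of these were in the imprinted lists. Of 32 measured genes listed as maternally expressed, 13 were called as listed, 2 the opposite way (Kcnq1 and Commd1, which hold the paternally expressed Kcnq1ot1 and Zrsr1 on the other strand) and 17 did not pass. Of 39 listed as paternally expressed, 29 were called as listed, 4 the opposite way (Gnasas1, Igf2, Phactr2 and Rtl1) and 6 did not pass. The 5 largest effects outside the lists were small RNAs or predicted transcripts inside known clusters, Gm38393 and Snord107 beside Snrpn with 0.0842% and 0.00% maternal reads, and Gm23474, Gm23508 and Mir770 inside Rian and Meg3 with 99.1%, 98.8% and 98.5%.

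The question of whether imprinting loosens with age was tested as a change of the maternal to paternal ratio. The clearest change lay on chromosome 7 between Snrpn and Ndn, inside the imprinted Prader-Willi domain. B230209E15Rik, a non-coding gene (chromosome 7, 61529871 to 61615327), had 0.968% ± 0.328 maternal reads in young mice (SD, n = 6) and 19.8% ± 3.44 in old mice (SD, n = 5), with 14.5% to 23.6% in the old mice of both crosses (edgeR adjusted p = 1.9e-14). Its maternal counts rose from 0.535 ± 0.131 to 11.9 ± 4.86 CPM of allelic reads, while its paternal counts measured 56.6 ± 8.97 in young and 47.1 ± 14.0 in old mice. Ube2nl, a short gene inside it, had 2.48% ± 1.24 and 28.0% ± 4.86 maternal reads, A330076H08Rik 1.07% ± 0.310 and 3.95% ± 1.40, and A230057D06Rik 1.58% ± 0.843 and 5.66% ± 2.62, in young and old mice. Snrpn, in the same imprinted domain, had 0.0870% ± 0.0647 and 0.0744% ± 0.0580, while A230006K03Rik (0.490% and 2.00%), Gm9801 (0.775% and 3.00%), Ndn (0.471% and 2.00%) and Snhg14 (2.28% and 2.87%) had a higher mean maternal share in old than in young mice without passing. For Snhg14 the maternal counts themselves did not rise (8.27 CPM of allelic reads in old and 8.86 in young mice).

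Of 24707 autosomal genes, 19 passed in the test of parental allele by age in edgeR, 12 with a higher maternal share in old mice and 7 with a lower one; limma on logit shares gave 8 and 11. Besides the 4 genes above, the 10 with the smallest p were Cyp20a1, Ncapd2, Scarna10, Gm28967, Ostc and Gm6793. Scarna10 and Gm28967 have identical counts and lie inside Ncapd2, so these 3 are 1 signal. Cyp20a1 had 73.4% to 76.0% BL6 reads in the 3 young mice with BL6 mothers and 51.9% to 59.5% in every other mouse. Cyp20a1 and Ncapd2 also passed in the test of strain allele by age (edgeR adjusted p = 0.0037 and 1.8e-04). Their age differences of the maternal share thus differed between the crosses. Counting the real one, 4 of 60 random groupings of the mice gave 19 or more genes, so the count itself is not above chance. The change at B230209E15Rik was called in all 16 settings run for it, while Ostc and Gm6793 each lost their call in 3. Both lost it without old replicate 3 and without the 3 libraries with the highest striatal markers. Of 32 maternally and 39 paternally listed genes measured, 1 passed, Commd1, with the same doubt about Zrsr1. Commd1 had 4.40% ± 1.55 maternal reads in young and 6.34% ± 0.7105 in old mice (edgeR adjusted p = 0.0398). With a BL6 mother its maternal reads overlapped between the ages, at 4.45% to 6.64% in young and 5.32% to 7.18% in old mice. With a CAST mother its paternal reads were 96.7% to 97.05% in young and 93.3% to 93.4% in old mice. The mean silent-allele share of the 21 core genes with a silent share under 10% was 2.31% ± 0.6252 in old mice and 1.85% ± 0.271 in young mice (SD, n = 5 and 6), a difference of 0.467 that did not pass an exact permutation test over 462 splits (two-sided p = 0.136). Without old replicate 3 the difference was 0.693 (exact permutation p = 0.0190), but Dlk1 alone, chosen after its values were seen, gave both differences their sign. It had 16.6% ± 9.46 maternal reads in old and 2.94% ± 1.79 in young mice, and left out it turned them to -0.193 and -0.145 (exact permutation p = 0.316 and 0.467). Other genes differed the other way: Meg3, Rian and Mirg had 1.90% to 4.1998% silent reads in the 3 young mice with CAST mothers and at most 0.611% in every other mouse. Sgce and Peg10, chosen after their values were seen, had 6.04% and 6.57% in young replicate 4 alone. With reads pooled over genes the difference was -0.540 (exact permutation p = 0.149), and with no limit on the silent share 0.0295 (p = 0.955).

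**Figure D3:**
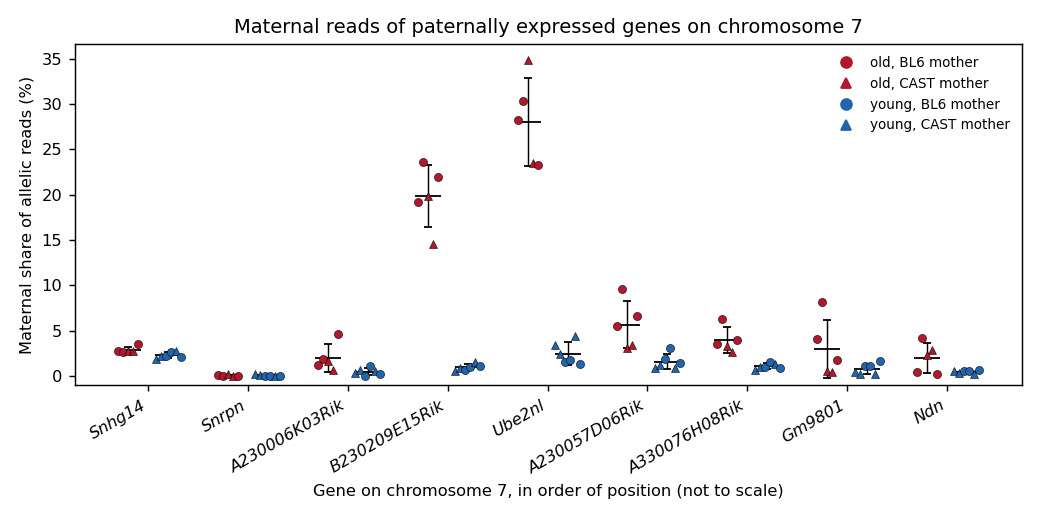
Maternal share of allelic reads, in percent, of 9 genes on chromosome 7 in order of position (not to scale), with a point per mouse (old red, young blue, circles BL6 mother, triangles CAST mother) and the mean and SD. B230209E15Rik runs from 14.5% to 23.6% in old mice and from 0.580% to 1.502% in young mice, and Snrpn reaches at most 0.183% in any mouse.

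Far more genes differed in allelic reads between the strains than between the parents. Of 24707 autosomal genes, 16174 differed between the BL6 and the CAST copy in edgeR, 10102 higher from BL6 and 6072 higher from CAST; with the total of each allele column as library size these were 8935 and 7009. The named genes with the largest effects were read almost entirely from 1 strain: Mir682, Rprl3, Mir703, Vmn2r85 and Vmn2r87 had 99.8% to 100.0% BL6 reads, and Hist1h2al, Cyp2c70, Sult3a1 and a pair of overlapping entries of Rprl1 had 0.00% to 0.347%. Most of these are members of multigene families or small RNAs, for which assignment to an allele can favour the reference strain. A bias towards BL6 cannot give the genes read from CAST. The way reads were assigned to alleles was not given in the sources used here, and bias at the other genes was not tested. How many of the 16174 calls reflect expression rather than read assignment is therefore not known.

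Some strain effects differed with age, foremost in a block of adjoining genes on chromosome 12 (79130777 to 79296304). Vti1b, a vesicle SNARE gene, had 40.7% ± 1.35 BL6 reads in young mice (SD, n = 6) and 24.9% ± 0.583 in old mice (SD, n = 5; edgeR adjusted p = 6.8e-14). Rdh11, a retinol dehydrogenase gene, went from 56.1% ± 1.35 to 38.8% ± 0.413, Zfyve26 from 51.3% ± 0.828 to 35.02% ± 0.717, Arg2, the mitochondrial arginase gene, from 34.4% ± 2.30 to 21.5% ± 1.56, and the predicted gene Gm48780 from 33.2% ± 5.44 to 17.7% ± 2.09. Total expression of Zfyve26 rose with age (log2 change 0.74, edgeR adjusted p = 0.0364). In 4 of the 5 old mice Nbr1, an autophagy receptor gene on chromosome 11, had 33.5% to 34.3% BL6 reads, against 49.6% in old replicate 4 and 49.6% to 50.5% in the young mice; the Wilson 95% interval in old replicate 1, which covers counting error only, was 33.2% to 34.4%. Ide, the insulin-degrading enzyme gene on chromosome 19, was chosen after its values were seen and had 69.7% to 71.4% in all old mice and 70.1% in young replicate 2, against 51.8% to 55.0% in the other young mice.

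In all, 41 of 24707 autosomal genes passed in the test of strain allele by age in edgeR, 23 with a higher and 18 with a lower BL6 share in old mice. The 10 with the smallest p held Vti1b, Zfyve26, Rdh11 and Arg2 of the block, Nbr1, Mlph, Pcdhb5 and the signal shared by Ncapd2, Scarna10 and Gm28967. Of these 10, only Mlph lost its call in any of 16 settings. It did so without the 3 libraries with the highest striatal markers (edgeR adjusted p = 0.0516). The count moved between 22 and 169 when single mice were left out, without old replicate 3 and without young replicate 5.

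**Figure D4:**
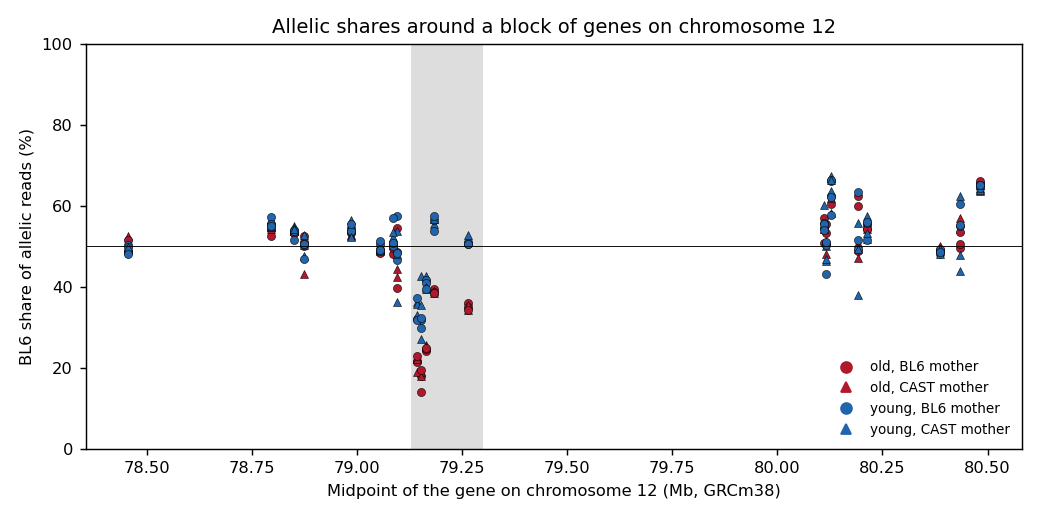
BL6 share of allelic reads, in percent, against the midpoint of each gene on chromosome 12 in Mb (GRCm38), for the 5 genes of the block (grey band) and the 8 nearest measured genes on each side, with a point per mouse. Old mice (red) lie below young mice (blue) at all 5 genes of the block, for example 24.9% against 40.7% on average at Vti1b, and the ages overlap at the neighbours drawn.

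Because each cell of a female silences 1 of its X chromosomes, the share of X-linked reads from the BL6 copy measures the balance of X inactivation in a mouse. The median BL6 share over 520 X-linked genes was 41.4% ± 7.58 in old mice (SD, n = 5) and 39.6% ± 11.8 in young mice (SD, n = 6), and the difference of 1.75 did not pass an exact permutation test (two-sided p = 0.797). Single mice ran from 20.3% in young replicate 1 to 56.5% in young replicate 3. Xist, the RNA made from the silenced X, ran the other way, with 81.2% BL6 reads in young replicate 1 and 46.7% in young replicate 3, and its mean was 60.8% ± 7.03 in old and 62.7% ± 11.4 in young mice (SD, n = 5 and 6). Tsix gave 60.2% and 62.9%, but it overlaps Xist and the strand setting was not given in the sources used here. Its share lay near that of Xist in single mice, with 81.2% in young replicate 1 and 46.8% in young replicate 3. It is therefore no measure separate from Xist. The X share was 45.5% ± 7.38 with a BL6 mother (SD, n = 6) and 34.3% ± 8.96 with a CAST mother (SD, n = 5), a difference of 11.2 (exact permutation, two-sided p = 0.0476); permuted within each age group the p was 0.0600. The p was over 0.05 in 9 of 11 removals of a single mouse, up to 0.124 by exact permutation without young replicate 1.

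The spread of the X share between mice, as the mean distance from the median of the age group, was 6.06 in old and 7.81 in young mice (exact permutation, two-sided p = 0.563). The median distance from 50% was 8.12 for genes that escape X inactivation and 11.5 for the other X-linked genes, a difference that was not tested, and Bgn, Mid1 and Ddx3x lay farther from 50% than 11.5. This distance does not separate a strain difference from the X share of a mouse. Over mice with X shares from 20.3% to 56.5%, Ddx3x ran from 26.5% to 41.9% BL6 reads. Bgn ran from 11.8% to 39.1% and Mid1 from 16.0% to 86.9%. Among the escape genes Kdm6a and Jpx had 48.1% ± 1.61 and 49.8% ± 2.89 BL6 reads in old mice and 48.0% ± 4.81 and 47.0% ± 5.28 in young mice (SD, n = 5 and 6), and Kdm5c 46.3% ± 3.74 and 44.1% ± 6.77. Ddx3x and Eif2s3x had 37.3% ± 3.04 and 39.1% ± 2.45 in old mice, 34.5% ± 5.71 and 38.5% ± 2.90 in young mice, and 5530601H04Rik, Pbdc1, Utp14a, Ftx, Car5b, Shroom4, Bgn and Mid1 had means between 26.6% and 55.6%. The age tests of the allelic ratio of 701 X-linked genes called 0 genes in edgeR, with 22 and 28 at an unadjusted p under 0.05 for the parental and the strain term. The smallest p belonged to G530011O06Rik, Gm15726 and Gm15247 for the parental term (edgeR adjusted p of 0.108, 0.1996 and 0.585) and to Asb11, Cdr1 and Dcx for the strain term (0.175, 0.673 and 0.743), none past the threshold.

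**Figure D5:**
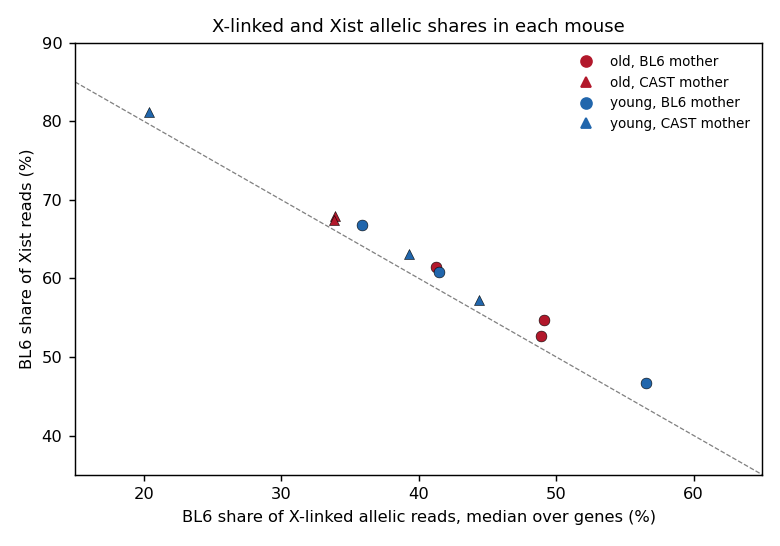
BL6 share of Xist reads against the median BL6 share of reads over 520 X-linked genes, both in percent, with a point per mouse (old red, young blue, circles BL6 mother, triangles CAST mother). The dashed line marks shares that add to 100%; the mice lie close to it, from young replicate 1 at 20.3% and 81.2% to young replicate 3 at 56.5% and 46.7%.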

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

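Each library was compared with the others of its age group by a Dixon test on the values of the genes and shares reported. Of 298 groups of values, 24 held an outlying library, against 14.9 by chance at 1 in 20, so many of them can be chance. The genes examined were chosen after the results were seen, because they are those the text names.

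In total counts, outlying values in TMM-scaled CPM were Zc3hav1 5.49, Col3a1 15.4 (both young replicate 5), Top2a 5.98 and Aspm 3.37 (both young replicate 2), C4a 6.32 (young replicate 6), Gadd45g 9.04 (young replicate 4), Lcn2 0.954 (old replicate 2) and Prkcd 213 (young replicate 1). The allelic reads of young replicate 4 were 35.12% of its total, the lowest share. Outlying BL6 shares were 49.6% for Nbr1 (old replicate 4), 14.1% for Gm48780 (old replicate 1), 32.1% for C4a (young replicate 6), 70.1% for Ide (young replicate 2), 60.5% for Shroom4 (young replicate 3) and 36.7% for Jpx (young replicate 1).

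Silent-allele shares stood out in old replicate 4 for Meg3, 0.531%, and Rian, 0.456%, below the 1.90% to 4.1998% of these genes in young mice with CAST mothers, in young replicate 4 for Sgce, 6.04%, and Peg10, 6.57%, in old replicate 5 for Snhg14, 3.48%, and in old replicate 3 for Snrpn, 0.177%. Maternal shares of Gm38393 were 0.175% in old replicate 3 and 0.226% in young replicate 1, and that of Mir770 was 99.7% in old replicate 2. The age difference of the maternal share differed between the crosses for Mest (edgeR adjusted p = 0.00263).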

How the results depend on the processing

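No paired analysis was possible because each number names one mouse. Where a count moved, the cause was not tested. Settings that leave out the libraries with striatal markers, or add a striatal or Malat1 term, were chosen after seeing the data.

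The 104 age calls were 17 at an adjusted p of 0.01, 522 in DESeq2 (272 higher, 250 lower), 47 with a minimum of 1 CPM, 3 in the BL6-mother cross alone and 0 in the CAST-mother cross alone, 10 in limma on TPM and 15 without young replicates 2 and 6 and old replicate 3. Of the 104, 67 stayed called with the striatal marker mean as a term and 80 with the Malat1 share as a term. Leaving out single mice gave 14 (old replicate 4) to 244 (young replicate 5), and every removal but that of young replicate 4 moved the count more than 1.5-fold. Onecut1, C4b, Spag6, Zc3hav1, Aspm, Gpr17, Itgax and Clec7a were called in all of 14 settings (DESeq2, RLE, no cross term and each mouse left out), while Dcx and Itgb2 were lost in 11, Mettl24 in 10, Uhrf1, Col3a1, Col1a2 and H2-Q7 in 9, Slc7a15, H2-D1, Ctss and Rrm2 in 8, Bmp4 in 7, Gpnmb and Rassf10 in 6, Eomes in 5, Top2a and Cenpf in 4, Lyz2 in 2, and C4a, Pcdhb2, Draxin and Cdkn2a in 1.

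The 63 calls by mother were 9 with a minimum of 1 CPM, 8 in young mice alone, 7 in old mice alone and 30 without the libraries with striatal markers; single mice gave 43 to 65. The interaction, with 0 calls, gave 52 in DESeq2 and 2 without a filter, and 0 to 2 with single mice left out (2 without old replicate 2). The correlation of the age effect between crosses ranged from -0.0576 (without young replicate 1) to 0.363 (without old replicate 3), and was -0.0242 without old replicate 4.

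With single mice left out, the 216 parental calls ranged from 208 to 239 and the 16174 strain calls from 14966 to 15870. With a minimum of 50 reads on average they were 157 and 13449, and with 10 reads in every mouse 176 and 14945. The 19 parental calls by age were 10 with a minimum of 50 reads (8 higher, 2 lower), 19 in limma (8 higher, 11 lower) and 12 without the libraries with striatal markers, and 11 (without old replicate 5) to 49 (without old replicate 2) with single mice left out; removing old replicates 1 and 3 or young replicates 3, 4 and 6 also moved it more than 1.5-fold. The 41 strain calls by age were 22 in limma and 23 without the libraries with striatal markers, and 22 (without old replicate 3) to 169 (without young replicate 5); removing old replicate 4 or young replicates 3, 4 and 6 moved it as well.

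With single mice left out, the silent-allele difference ranged from 0.291 (without old replicate 1) to 0.693 (without old replicate 3). It was -0.540 with reads pooled over genes, 0.0295 with no limit on the silent share, 0.334 with the full imprinted lists and -0.193 without Dlk1, or -0.145 without Dlk1 and old replicate 3, a pair of settings chosen after seeing the data. The X share difference ranged from -2.11 to 5.14 and its spread from -2.87 to 0.897. The X share difference by mother, 11.2, ranged from 7.70 (without young replicate 1) to 13.7 (without young replicate 5), and its p was 0.0600 by exact permutation within age groups and over 0.05 in 9 of 11 removals, up to 0.124. The X-linked test by age gave 3 calls with the mouse total as library size and 0 to 5 with single mice left out (5 without young replicate 6).

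The 23 lists were 4 with an estimated correlation and 9 in fry, and 17 to 30 with single mice left out. The lists of aging microglia, newborn neurons, complement and DNA methylation enzymes passed in all 18 settings run for lists, none of them in a single cross. In 3 cases the list test, which follows the mean, turned direction: for thalamus without young replicate 1 (median 0.449, range from -0.314 without old replicate 5), for oxidative phosphorylation with the Malat1 share as a term (median -0.0822), both past the test, and for striatum with the striatal mean as a term, where the median was -0.0284 and the list no longer passed.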

Other observations

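The tests of explanations below were written after the results were seen, and the random groupings of the mice were planned before. In old hippocampus C4b and Itgax were higher, and the lists of newborn neurons and of DNA methylation enzymes were lower, in all 14 settings run for genes and 18 run for lists. The age change of the parental ratio with the smallest p lay at B230209E15Rik, while Snrpn had 0.0744% maternal reads in old mice. Dlk1, chosen after its values were seen, had 16.6% ± 9.46 maternal reads in old and 2.94% ± 1.79 in young mice (SD, n = 5 and 6), with 1.53% in old replicate 3, and did not pass (edgeR adjusted p = 0.515).

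All 5 old mice read more from the CAST copy of a block of genes on chromosome 12, where the median log2 difference of CAST-allele counts over the block was 0.848, near that of an added copy, against -0.0200 for the neighbours, and the BL6 copy differed by -0.197. By gene the CAST copy ran from 0.63 to 1.12 and the BL6 copy from -0.54 to 0.15, and a lower BL6 copy, as at Gm48780 and Arg2, is not what an added CAST copy gives. A candidate explanation is a duplication that segregates in the CAST stock and that the old cohort carried. Nbr1 had a stepped share with more CAST reads too (CAST copy 0.67 and BL6 copy -0.11 on the log2 scale), at 49.6% in old replicate 4 alone. Beside it, Tmem106a had 50% in old replicate 4 and at most 28.5% in the other old mice (CAST copy 1.27, BL6 copy -0.12). Ide, stepped at 70.1% in young replicate 2, differed on the BL6 copy instead (0.73, CAST copy -0.16), which an added CAST copy cannot give. Btaf1, near Ide, was stepped in the same mice (BL6 copy 0.22, CAST copy -0.25). It had 62.1% in young replicate 2 and 51.1% to 53.99% in the other young mice. Whether a BL6 copy was added there was not tested. Genotypes of the parents would decide whether copies were added. The nearest measured gene above the chromosome 12 block lies 811 kb away, and age and cohort cannot be separated here.

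At B230209E15Rik, maternal reads rose in old mice of both crosses. A mixed sample is unlikely. The median silent share in old mice was 0.230% over the 8 imprinted genes with under 1% in young mice, and 0.395% over all 21 core genes. The 1 annotated gene with counts that overlaps it, Ube2nl, had maternal counts in old mice equal to 3.18% of the added ones. Ube2nl changed in the same way, and the strand setting was not given, so this cannot exclude reads of a transcript outside the annotation. Partial loss of silencing of the maternal copy in some cells may explain the change, or a shift in cell types that express it from both copies, and neither was tested. Snrpn did not follow, whereas A230006K03Rik, Gm9801 and Ndn had higher mean maternal shares in old mice without passing. Single mice overlapped between the ages. Old and young mice had 0.614% to 4.58% and 0.00% to 1.15% at A230006K03Rik, and 0.468% to 8.12% and 0.171% to 1.65% at Gm9801. At Ndn they had 0.210% to 4.15% and 0.234% to 0.623%. How far the change reaches stays open.

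Part of the 63 calls by mother strain in total counts may come from read placement. Of the 13 calls outside the clusters of chromosomes 7 and 12, 9 (69.2%) match a mitochondrial transcript. For these 9, reads of the maternally inherited mitochondrial genome placed on nuclear copies could give this pattern. In the small nucleolar RNA cluster, 97.9% of calls were higher where the father was BL6, which could reflect CAST copies that were not counted, while Snrpn, which would need to stay level, differed by -0.23 (SE 0.14) and Ndn by -0.77 (SE 0.25), lower with a CAST mother and so opposite to the cluster. The explanation stays open.

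Random groupings of the mice, counting the real one, gave as many calls in 3 of 100 for age (104 calls, highest other 3918), 1 of 100 for mother (63, highest other 4), 1 of 57 for the parental allele (216, highest other 4), 4 of 60 for the parental allele by age (19, highest other 148), 2 of 60 for the strain allele by age (41, highest other 85), 100 of 100 for X-linked genes (0, highest other 16) and 13 of 100 for lists (23, highest other 27). The grouping with 3918 calls put together old replicate 3 and young replicates 1, 2, 3 and 6. Most of these hold markers of striatum, thalamus or choroid plexus. Young replicate 3 had 1.13 CPM of Drd2 and 13.5 CPM of Ttr, but 6.07 CPM of the cerebellar gene Cbln3. Markers of other tissue were not limited to this grouping, with 880 CPM of Ttr in old replicate 2 and 6.82 CPM of Cbln3 in young replicate 4. The libraries of the grouping were also the lowest in Fibcd1 and Prox1. The young ones among them had the highest Malat1 shares, 1.76% to 2.005%. Dissection, or what goes with the Malat1 share, may have shaped total counts more than age did, and the 2 were not told apart. The number of parental calls by age and the number of lists may therefore be chance, as 4 of 60 and 13 of 100 groupings matched them.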
